A study of Homo sapiens with 4 samples.

How the data were processed

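Total RNA was sequenced from human umbilical vein endothelial cells infected with an adenovirus that carried SREBP2 (Ad-SREBP2, 2 libraries) or an empty vector (Ad-Null, 2 libraries), 72 hr after infection at 70% confluency. Groups and replicate numbers were taken from the library titles. The deposited file lists FPKM values for 26006 loci. Its header names no unit, so FPKM was inferred from the values (decimals from 0 upward, sums that differ between libraries, and a step per fragment that differs from gene to gene) together with the tools in the submitters' processing notes. These notes name bcl2fastq, TopHat2 2.0.14, Cufflinks 2.2.1 and the build hg19, without the role of each. Filters, annotation and any scaling between libraries are not given in the sources used here. Coordinates are not given because the reference at hand was of another build.

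Read counts were not used here. The relative depth of a library was read from loci with values up to 0.05 FPKM, as the ratio to Ad-Null replicate 1 that recurred most often within a relative tolerance of 0.0005, and ranged from 0.919 to 1.22. Counting error of single loci was not computed. XIST and Y-linked genes were removed, which left 25897 loci. Loci that hold more than 1 symbol (616) were kept whole under all their symbols. Exonic lengths were taken by symbol from GENCODE v29 on GRCh38, while the values were made on hg19.

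Values were analysed as log2(FPKM + 1), with R 4.3.3 and limma 3.58.1. The 11770 loci with a mean of at least 1 FPKM over the 4 libraries were fitted (lmFit, then eBayes with a trend of variance on mean level) with the group as the only term. Tests were 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 libraries per group, an exact permutation test of 1 gene cannot go under 0.333. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

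The groups, tests, alternatives and 37 gene lists (697 entries) were fixed before the data were examined. Of these lists, 35 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera refers its statistic to the few residual degrees of freedom of 4 libraries, so its power was low whatever the correlation. Members were also adjusted over the list alone. The lists cover cholesterol synthesis, sterol uptake and feedback, fatty acid synthesis, LXR targets, endothelial identity, flow response, mesenchymal transition, TGF-beta and BMP signalling, matrix, leukocyte adhesion and cytokines, inflammasome and NADPH oxidases, interferon response, antigen presentation, mitosis, DNA replication, p53 targets, unfolded protein response, NRF2 and oxidative response, heat shock, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, histones, Notch and arterial genes, venous and lymphatic genes, angiogenesis, haemostasis, vasoactive genes, YAP targets, immediate early genes, lysosome and autophagy, apoptosis, SREBP2 processing, and markers of smooth muscle, fibroblasts, leukocytes and epithelium. The 12 lists described in full were chosen after a first look at the list results.

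Genes were named by a rule: SREBF2; then up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold without overlap between the groups, small RNA loci left out, or, with fewer than 12, all that passed and the next by smallest p up to 5; then up to 4 members of each described list by smallest p, and up to 8 for cholesterol synthesis, sterol uptake, endothelial identity and mesenchymal genes. PMVK, SCAP, GPAM, ABCA1, ABCG1, VEGFA, CCNB1, FN1, CXCL8, LUM, KRT19, KRT7, the 3 small RNA loci and the genes named in the closing section were named after their values were seen. Some single-gene results, including ones that this rule names, are not reported and not named in the figures, and these genes stay in the counts, medians and tests.

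The fit was tested on simulated data with 11770 genes, of which 200 changed, in 5 runs. With both groups spread like Ad-Null, 98.4% of 2-fold changes were called. With each group spread as observed, 1.2% of 2-fold, 37.6% of 4-fold, 87.2% of 8-fold and 98% of 16-fold changes were called. Each simulated gene had the typical spread of genes at its level. Strongly raised genes could differ more between the Ad-SREBP2 libraries, so these shares may not hold for them. DHCR7, at log2 changes of 4.00 and 5.96 in Ad-SREBP2 replicates 1 and 2, was not called in the data (limma adjusted p = 0.508). Of unchanged genes 0.07% to 0.08% were called. A list of changed genes was called in 5 of 5 runs and a list of unchanged genes in 0. The simulated genes varied independently of each other. These runs therefore cannot show how often camera calls an unchanged list whose members move together. In the data the estimated correlation was 0.742 for cholesterol synthesis and 0.983 for ribosomal proteins, but 0.004 for interferon response.

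Alternatives were pseudocounts of 0.1 and 0.01, no filter on low values, a mean of at least 5 FPKM, upper-quartile scaling, quantile normalization, no variance trend, the replicate number as a block, and each library left out in turn. Fits without small RNA loci, with limma's arrayWeights, and without small RNA loci and 1 Ad-SREBP2 library were added after the data were seen.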

Results

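RNA was sequenced from human umbilical vein endothelial cells (HUVECs), primary cells that line the umbilical vein, 72 hr after adenoviral infection at 70% confluency. The virus carried SREBP2, named SREBP2(N) in the series title, or an empty vector (Ad-Null). Each group had 2 libraries. The labels call them biological duplicates and do not say whether they came from separate donors or cultures, so the p-values measure only the spread between these libraries. Expression was given in FPKM (fragments per kilobase of transcript scaled to library depth, a unit inferred from the values) for 26006 loci, and the 11770 loci with a mean of at least 1 FPKM over the 4 libraries were tested. FPKM summed to 482167 and 431621 in Ad-Null replicates 1 and 2, and to 466097 and 399742 in Ad-SREBP2 replicates 1 and 2. Read totals were not used here. Steps between low values put the depth of the other libraries at 1.22 (Ad-Null replicate 2), 1.10 (Ad-SREBP2 replicate 1) and 0.919 (Ad-SREBP2 replicate 2) times that of Ad-Null replicate 1.

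The comparison asks which transcripts differ in endothelial cells that carry extra SREBP2, the transcription factor that switches on genes of cholesterol synthesis and uptake. SREBF2, the gene that encodes SREBP2 (locus XLOC_015642), stood at 16.4 ± 0.421 FPKM in Ad-Null (SD, n = 2) and at 149 ± 129 FPKM in Ad-SREBP2 (SD, n = 2). The SREBP2 libraries differed from each other: SREBF2 was at 57.7 FPKM in replicate 1, 3.53 times the Ad-Null mean, and at 240 FPKM in replicate 2, 14.7 times that mean. Reads of the virus and of the cell's own SREBF2 were not separated, so these values do not give the amount of SREBP2 delivered. The log2 change of SREBF2 in Ad-SREBP2 against Ad-Null was 2.78 (SE 0.70), with no overlap between the groups, and it missed the threshold in limma (adjusted p = 0.760). It passed when either Ad-SREBP2 library was left out, at a log2 change of 3.80 (limma adjusted p = 0.000581) without replicate 1 and 1.76 (limma adjusted p = 0.0179) without replicate 2. In such a fit the lone library left in a group is assumed to vary like the other group.

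Genes of cholesterol synthesis were higher in Ad-SREBP2 in 19 of 20 members, with no overlap between the groups, where chance gives 16.7% in a given direction. That share holds for 1 gene on its own. Members that move together (estimated correlation 0.742 here) can separate as a block, so such counts, here and for the lists below, are not independent trials. The median log2 change of the list was 3.83, at 2.87 in replicate 1 and 4.76 in replicate 2, against a difference of 0.102 between the Ad-Null libraries. DHCR7, which makes cholesterol from its last precursor, stood at 5.64 ± 0.0695 FPKM in Ad-Null and 259 ± 218 FPKM in Ad-SREBP2 (SD, n = 2 each), 18.7 and 73.3 times the Ad-Null mean in the SREBP2 replicates. MVD, the mevalonate diphosphate decarboxylase, was at 5.99 ± 0.185 against 113 ± 29.6 FPKM (SD, n = 2 each). IDI1, the isopentenyl diphosphate isomerase, was at 11.2 ± 0.317 against 623 ± 603 FPKM (SD, n = 2 each). The log2 changes were 4.98 (SE 0.68) for DHCR7, 4.00 (SE 0.28) for MVD and 5.22 (SE 0.82) for IDI1. MSMO1, ACAT2 and MVK had log2 changes of 4.06, 5.48 and 4.50. The exception was PMVK, the phosphomevalonate kinase, at 16.4 and 13.5 FPKM in Ad-Null and 15.5 and 11.5 FPKM in Ad-SREBP2. With limma, 0 of the 20 genes passed over all genes tested and 19 rose when adjusted over the list alone. Over all genes tested, 19 of the 20 rose without Ad-SREBP2 replicate 1 and 16 without replicate 2. The list rose in camera with a preset correlation (adjusted p = 5.32e-35), and this call was lost at adjusted p = 0.474 with an estimated correlation.

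**Figure D1:**
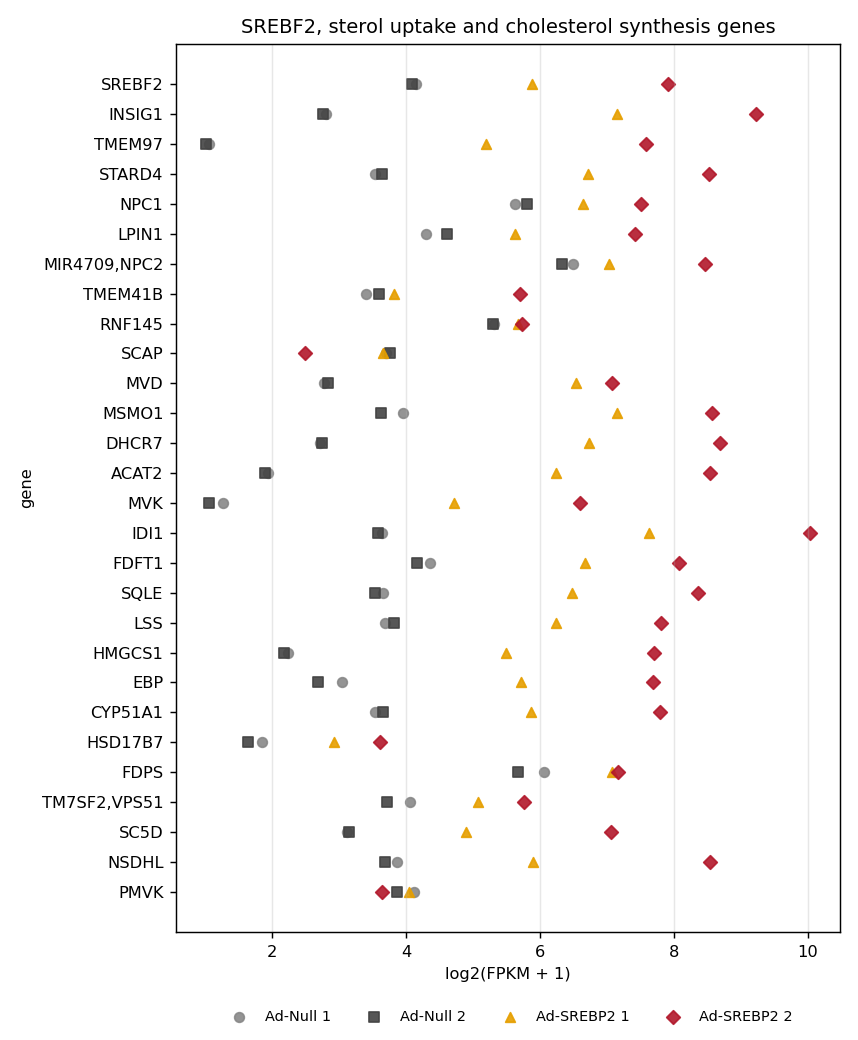
Expression of SREBF2, 9 other sterol uptake and feedback loci and 18 cholesterol synthesis loci, as log2(FPKM + 1) on the horizontal axis. Each marker is 1 library (circles and squares, Ad-Null; triangles and diamonds, Ad-SREBP2 replicates 1 and 2), and MVD lies at 5.86 and 6.12 FPKM in Ad-Null and 91.6 and 133 FPKM in Ad-SREBP2, while PMVK overlaps between the groups.

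Sterol uptake and feedback genes were higher without overlap in 11 of 12 members (chance 16.7%), of which SREBF2 itself is 1, at a median log2 change of 2.30 (1.46 in replicate 1, 3.10 in replicate 2). INSIG1, which holds SREBP precursors in the endoplasmic reticulum, was at 5.85 ± 0.156 FPKM in Ad-Null and 370 ± 325 FPKM in Ad-SREBP2 (SD, n = 2 each), a log2 change of 5.41 (SE 0.71). STARD4, a sterol carrier, was at 11.1 ± 0.610 against 236 ± 187 FPKM (SD, n = 2 each). TMEM97, NPC1 and LPIN1 had log2 changes of 5.36, 1.36 and 2.06, and LPIN1 is also a member of the fatty acid list. SCAP, the escort protein of SREBPs, was lower without overlap, at 12.3 ± 0.411 FPKM in Ad-Null and 8.13 ± 4.98 FPKM in Ad-SREBP2 (SD, n = 2 each). In limma 8 of the 12 rose when adjusted over the list alone (6 with either Ad-Null library left out) and 0 passed over all genes tested. Over all genes tested, 10 rose and SCAP fell without Ad-SREBP2 replicate 1, and 6 rose without replicate 2. The list rose in camera (adjusted p = 1.79e-14), a call lost at adjusted p = 0.474 with an estimated correlation.

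Fatty acid synthesis genes were higher without overlap in 15 of 16 members (chance 16.7%), at a median log2 change of 2.42 (1.54 in replicate 1, 3.27 in replicate 2). SCD, the desaturase that makes oleate, was at 20.7 and 19.3 FPKM in Ad-Null and 461 and 2025 FPKM in Ad-SREBP2. FADS2, a desaturase of polyunsaturated fatty acids, was at 4.73 ± 0.0496 against 212 ± 71.3 FPKM, and FASN, the fatty acid synthase, at 26.2 ± 5.79 against 267 ± 185 FPKM (SD, n = 2 each). ACSS2, which makes acetyl-CoA from acetate, had a log2 change of 4.09 (SE 0.58). GPAM, an acyltransferase of glycerolipid synthesis, was at 2.73 and 2.98 FPKM in Ad-Null and 2.63 and 2.74 FPKM in Ad-SREBP2. In limma 13 of the 16 rose when adjusted over the list alone (8 without Ad-Null replicate 1) and 0 passed over all genes tested, where 15 rose without Ad-SREBP2 replicate 1 and 8 without replicate 2. The list rose in camera (adjusted p = 7.91e-23), a call lost at adjusted p = 0.474 with an estimated correlation.

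Over all genes, 1 locus was higher and 2 were lower in Ad-SREBP2 (limma, Benjamini-Hochberg adjusted p = 0.0338 for each). All 3 were small RNA loci listed at 0 in one group: SNORD105, at 31.5 and 37.8 FPKM in Ad-SREBP2, and MIR126 and MIR4517, at 34.7 and 28.5 FPKM and at 46.4 and 38.1 FPKM in Ad-Null. In all 3, each value above 0, scaled for depth, was 1.0 to 1.052 times the value taken as 1 fragment. That value was the median of the lowest values of small RNA loci of similar length, the called locus included. At an unadjusted p under 0.05, 187 loci were higher and 57 lower. The genes outside small RNA loci with the smallest p, none of which passed, were FADS2 (limma adjusted p = 0.0729), MVD (0.0941), FABP3 (0.163) and the locus ANKRD54,MIR658 (0.164) among those that were higher. FABP3, a fatty acid carrier, was at 0.388 ± 0.334 FPKM in Ad-Null and 93.8 ± 55.6 FPKM in Ad-SREBP2 (SD, n = 2 each). The locus ANKRD54,MIR658 was at 7.34 ± 0.598 against 55.2 ± 5.28 FPKM (SD, n = 2 each), and reads of its 2 symbols were not separated. Among those that were lower, ANGPT2, UBE2C, CHRNA1, MAD2L1 and CDC20 had the smallest p (limma adjusted p = 0.760 for each). ANGPT2, a vessel-destabilizing ligand of the TIE2 receptor, was at 28.9 ± 6.65 FPKM in Ad-Null and 7.15 ± 2.02 FPKM in Ad-SREBP2, and CHRNA1, a subunit of the muscle acetylcholine receptor, at 3.59 ± 0.521 against 0.728 ± 0.519 FPKM (SD, n = 2 each).

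Outside small RNA loci, 1849 of 11603 genes were higher without overlap (15.9%) and 2721 were lower (23.5%), where chance gives 16.7% in a given direction. The median log2 change of all tested loci was -0.12. The Ad-SREBP2 libraries lay farther from each other than the Ad-Null libraries did. The SD of the log2 difference over the tested genes was 0.943 between them and 0.422 between the Ad-Null libraries. Across genes, which are not independent replicates, Pearson r was 0.864 for the Ad-SREBP2 pair and 0.973 for the Ad-Null pair, and replicate 2 of Ad-SREBP2 had r of 0.818 and 0.828 with the Ad-Null libraries against 0.970 and 0.961 for replicate 1. Without Ad-SREBP2 replicate 1 the limma counts were 1976 higher and 3028 lower, and without replicate 2 they were 72 higher and 9 lower. With either Ad-Null library left out, 0 loci passed in each direction in limma, with 106 higher and 48 lower (without replicate 1) and 87 higher and 39 lower (without replicate 2) at an unadjusted p under 0.05. In a fit chosen after the data were seen, which left out small RNA loci and gave the more variable group less weight, 32 genes rose and 0 fell (557 higher and 126 lower at an unadjusted p under 0.05), and 23 of the 32 belonged to the 3 lists of cholesterol synthesis, sterol uptake and fatty acid synthesis. Among them were INSIG1, MVD and FADS2. The counts without Ad-SREBP2 replicate 1 were out of 11756 loci, a general share to set beside the list counts from that fit. An exact permutation test of a single gene in 2 against 2 libraries cannot give a 2-sided p under 0.333.

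**Figure D2:**
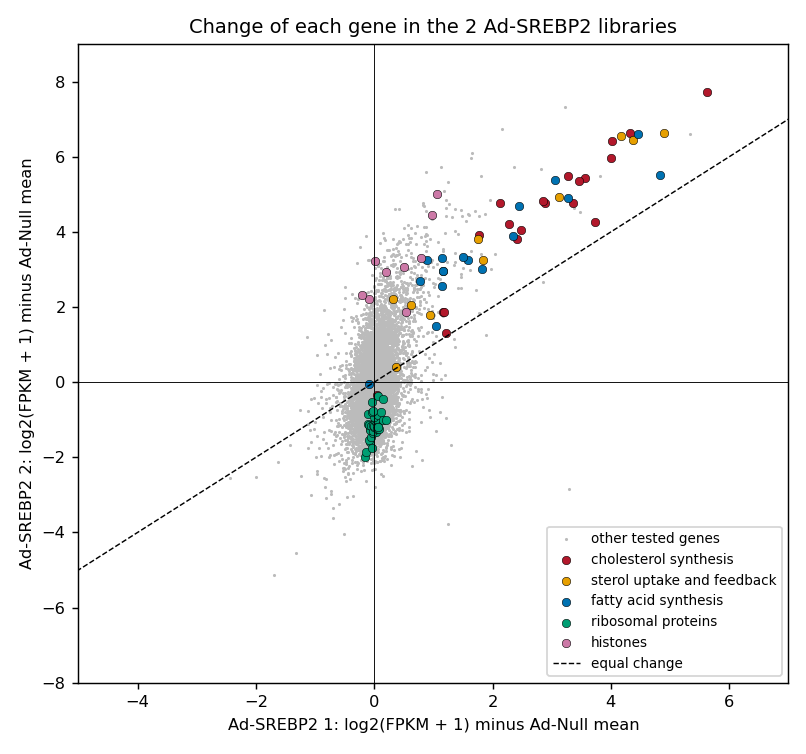
Change of each tested gene, without small RNA loci, in Ad-SREBP2 replicate 1 (horizontal axis) and replicate 2 (vertical axis), each as log2(FPKM + 1) minus the mean of the Ad-Null libraries. Each point is 1 gene, colours mark 5 gene lists and the dashed line is equal change; the SD of the change is 0.316 in replicate 1 and 1.01 in replicate 2, and the sterol and fatty acid genes other than PMVK, GPAM and SCAP lie to the upper right.

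Of the 35 gene lists tested, 15 rose and 4 fell in camera with a preset correlation, and 0 did so with an estimated correlation, where the smallest adjusted p was 0.474. These losses alone do not show that members moved together. The interferon and LXR lists had estimated correlations of 0.004 and -0.027, below the preset 0.01. Their unadjusted camera p was 0.0245 and 0.0399 with the estimate, against 3.83e-09 and 3.69e-06 at the preset. Targets of LXR, the oxysterol-activated receptor of cholesterol efflux, rose at a median log2 change of 0.54 (camera adjusted p = 2.15e-05; adjusted p = 0.474 with an estimated correlation). APOC1, an apolipoprotein, was at 0 and 0.288 FPKM in Ad-Null and 2.86 and 3.05 FPKM in Ad-SREBP2. SREBF1, which encodes the lipogenic relative of SREBP2, was at 20.8 ± 1.17 against 52.0 ± 11.2 FPKM, and LPCAT3, a phospholipid-remodelling acyltransferase, at 6.92 ± 0.146 against 44.7 ± 38.4 FPKM (SD, n = 2 each). SREBF1 also belongs to the sterol or fatty acid lists and to the SREBP2 processing list, so its rise does not speak for LXR alone. MYLIP, a ubiquitin ligase induced by LXR, had a log2 change of 0.54. In limma APOC1 and SREBF1 rose when adjusted over the list alone, and 0 of 11 passed over all genes tested. With either Ad-Null library left out, or at a pseudocount of 0.1 or 0.01, 0 of 11 passed over the list alone. Without Ad-SREBP2 replicate 1, 5 rose and 1 fell both over the list alone and over all genes, and without replicate 2, 3 rose over the list alone and 0 over all genes. ABCA1, the cholesterol exporter, was at 5.91 and 10.2 FPKM in Ad-Null and 11.7 and 10.5 FPKM in Ad-SREBP2, and its partner ABCG1 was at 29.7 and 28.1 against 32.9 and 13.6 FPKM.

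Interferon response genes were higher without overlap in 16 of 26 members, where chance gives 16.7%, and the list rose at a median log2 change of 0.55 (0.46 in replicate 1, 0.61 in replicate 2; camera adjusted p = 3.35e-08). That call was lost at adjusted p = 0.474 with an estimated correlation, and 0 of 26 passed in limma over all genes tested or adjusted over the list alone. Without Ad-SREBP2 replicate 1, 16 rose and 3 fell over the list alone and 12 rose and 2 fell over all genes, and without replicate 2, 5 rose over the list alone and 0 over all genes. OASL, an antiviral protein induced by interferon, was at 0.677 ± 0.413 FPKM in Ad-Null and 5.94 ± 3.56 FPKM in Ad-SREBP2, and IFIT2, of the same response, at 0.970 ± 0.322 against 8.99 ± 7.87 FPKM (SD, n = 2 each). IFIT3 and IFIT1 had log2 changes of 1.66 (SE 0.54) and 1.35 (SE 0.47).

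Flow-responsive protective genes rose as a list, at a median log2 change of 0.59 (camera adjusted p = 0.000365; adjusted p = 0.491 with an estimated correlation), with 7 of 11 higher and 1 lower without overlap (chance 16.7% in a given direction). KLF2 and KLF4, transcription factors induced by laminar flow, were at 35.7 ± 5.92 against 81.7 ± 42.6 FPKM and at 21.5 ± 0.565 against 40.0 ± 10.9 FPKM (SD, n = 2 each). NQO1, a quinone reductase, was at 63.8 ± 6.42 against 98.7 ± 16.7 FPKM, and SLC7A2, an arginine transporter, at 27.6 ± 16.6 against 10.6 ± 4.47 FPKM (SD, n = 2 each). None of the 11 passed in limma over all genes tested or adjusted over the list alone. The list median was 0.786 without Ad-SREBP2 replicate 1 and 0.506 without replicate 2.

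Angiogenesis and tip-cell genes fell as a list, at a median log2 change of -0.89 (-0.14 in replicate 1, -1.33 in replicate 2; camera adjusted p = 0.00794; adjusted p = 0.810 with an estimated correlation). Of the 15 members, 9 were lower without overlap (chance 16.7%, and 23.5% of all genes outside small RNA loci). The median was -0.50 without Ad-Null replicate 1 and -0.585 without Ad-Null replicate 2. CXCR4, the chemokine receptor of tip cells, was at 128 ± 46.1 FPKM in Ad-Null and 26.7 ± 31.6 FPKM in Ad-SREBP2 (SD, n = 2 each). PDGFB, which recruits pericytes, was at 44.6 ± 3.76 against 14.8 ± 10.5 FPKM, and PGF, the placental growth factor, at 244 ± 35.4 against 85.8 ± 88.8 FPKM (SD, n = 2 each). VEGFA and FLT1 were higher without overlap, VEGFA at 83.1 ± 6.42 FPKM in Ad-Null and 119.6 ± 34.7 FPKM in Ad-SREBP2 (SD, n = 2 each). ANGPT2 alone fell when adjusted over the list alone (limma adjusted p = 0.0333), which it did not with either Ad-Null library left out or with no filter on low values, and 0 of 15 passed over all genes tested. Leaving out Ad-SREBP2 replicate 1, 10 fell and 1 rose over the list alone and 8 fell and 1 rose over all genes, and leaving out replicate 2, 3 fell and 1 rose over the list alone and 0 passed over all genes.

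Mitosis genes fell as a list (median log2 change -0.38, camera adjusted p = 0.00794; adjusted p = 0.810 with an estimated correlation). UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, was at 9.56 ± 5.68 FPKM in Ad-Null and 1.07 ± 0.533 FPKM in Ad-SREBP2, and CDK1, the mitotic kinase, at 3.97 ± 1.39 against 0.967 ± 0.512 FPKM (SD, n = 2 each). CDC20 and NDC80 had log2 changes of -1.54 and -1.18, as had MAD2L1, a checkpoint gene outside the list, of -1.13, and 0 of 18 list members passed in limma over all genes or adjusted over the list alone. All 18 were lower in Ad-SREBP2 replicate 1 than in both Ad-Null libraries, and all 18 were also higher in Ad-Null replicate 2 than in replicate 1. In Ad-SREBP2 replicate 2 the members went apart, with CCNB1 at 26.4 FPKM against 3.04 and 4.47 FPKM in Ad-Null. The call was lost without Ad-SREBP2 replicate 1 (median -0.08, camera adjusted p = 0.563) and without Ad-Null replicate 2 (median 0.02, camera adjusted p = 0.283), and at a mean of at least 5 FPKM (median 0.07, camera adjusted p = 0.725). Without Ad-Null replicate 2 and at 5 FPKM the median was above 0 while the camera direction was lower, and without Ad-SREBP2 replicate 1 the direction was higher. At 5 FPKM only 3 members were left to test, of which 1 fell over the list alone. With no filter on low values 25 members were tested and the list fell (median -0.42, camera adjusted p = 2.78e-06). The median was -0.79 without Ad-Null replicate 1 and -0.86 without Ad-SREBP2 replicate 2. Without Ad-SREBP2 replicate 1, 4 members fell and 2 rose, both over the list alone and over all genes, and without Ad-Null replicate 1, 1 member fell over the list alone.

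Endothelial identity genes did not pass as a list (median log2 change -0.33, camera adjusted p = 0.652), and the replicates differed, at 0.19 in replicate 1 and -0.85 in replicate 2. In 18 of the 23 genes Ad-SREBP2 replicate 2 was below every other library. ROBO4, a receptor of the endothelium, was at 135 ± 6.96 FPKM in Ad-Null and 91.3 ± 58.0 FPKM in Ad-SREBP2, TIE1 at 215 ± 52.6 against 154 ± 101 FPKM, and the transcription factors SOX18, ERG and FLI1 at 19.3 ± 5.62 against 12.7 ± 10.2, 44.7 ± 2.55 against 34.6 ± 12.7 and 23.7 ± 2.21 against 18.6 ± 8.30 FPKM (SD, n = 2 each). PLVAP, a component of fenestral diaphragms, was higher without overlap, at 6.06 ± 4.25 against 14.5 ± 1.36 FPKM, as was FLT1, at 41.3 ± 3.64 against 51.2 ± 1.17 FPKM (SD, n = 2 each). MMRN1 had a log2 change of -0.62 (SE 0.56). Without Ad-SREBP2 replicate 2 the list rose (median 0.19, camera adjusted p = 0.00734) and without Ad-Null replicate 2 it fell (median -0.49, camera adjusted p = 0.0361), with a median of -0.175 without Ad-Null replicate 1. In limma 0 of 23 passed over all genes tested or adjusted over the list alone, and without Ad-SREBP2 replicate 2 the log2 changes of SOX18, TIE1, MMRN1 and FLI1 were 0.07, 0.09, 0.05 and 0.05. Leaving out replicate 1 instead, these changes were -1.61, -1.35, -1.30 and -0.85.

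Mesenchymal genes used to read endothelial-to-mesenchymal transition did not pass as a list either (median log2 change -0.35, camera adjusted p = 0.438). Of the 15 tested, 7 were lower and 1 higher without overlap (chance 16.7% in a given direction). Of all genes outside small RNA loci, 23.5% were lower and 15.9% higher in this way. The median was -0.15 without Ad-SREBP2 replicate 2, -0.18 without Ad-Null replicate 2 and -0.07 with no filter on low values. VIM, the intermediate filament vimentin, was at 1613 ± 200 FPKM in Ad-Null and 895 ± 673 FPKM in Ad-SREBP2 (SD, n = 2 each). ACTA2, smooth muscle actin, was at 4.43 ± 0.641 against 2.69 ± 1.59 FPKM, and ZEB1, a transcription factor of the transition, at 53.4 ± 5.56 against 37.3 ± 13.2 FPKM (SD, n = 2 each). TGFBI and ZEB2 had log2 changes of -0.60 and -0.35, and S100A4 was at 1.91 ± 0.0148 against 2.70 ± 0.304 FPKM (SD, n = 2 each). CNN1, a smooth muscle calponin, was at 5.70 FPKM in Ad-SREBP2 replicate 2 and at 0.0327 FPKM or less in the other libraries. None of the 15 passed in limma over all genes tested or adjusted over the list alone. The list median was -0.34 without Ad-SREBP2 replicate 1. FN1, fibronectin, was at 544 and 927 FPKM in Ad-Null and 640 and 1006 FPKM in Ad-SREBP2.

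**Figure D3:**
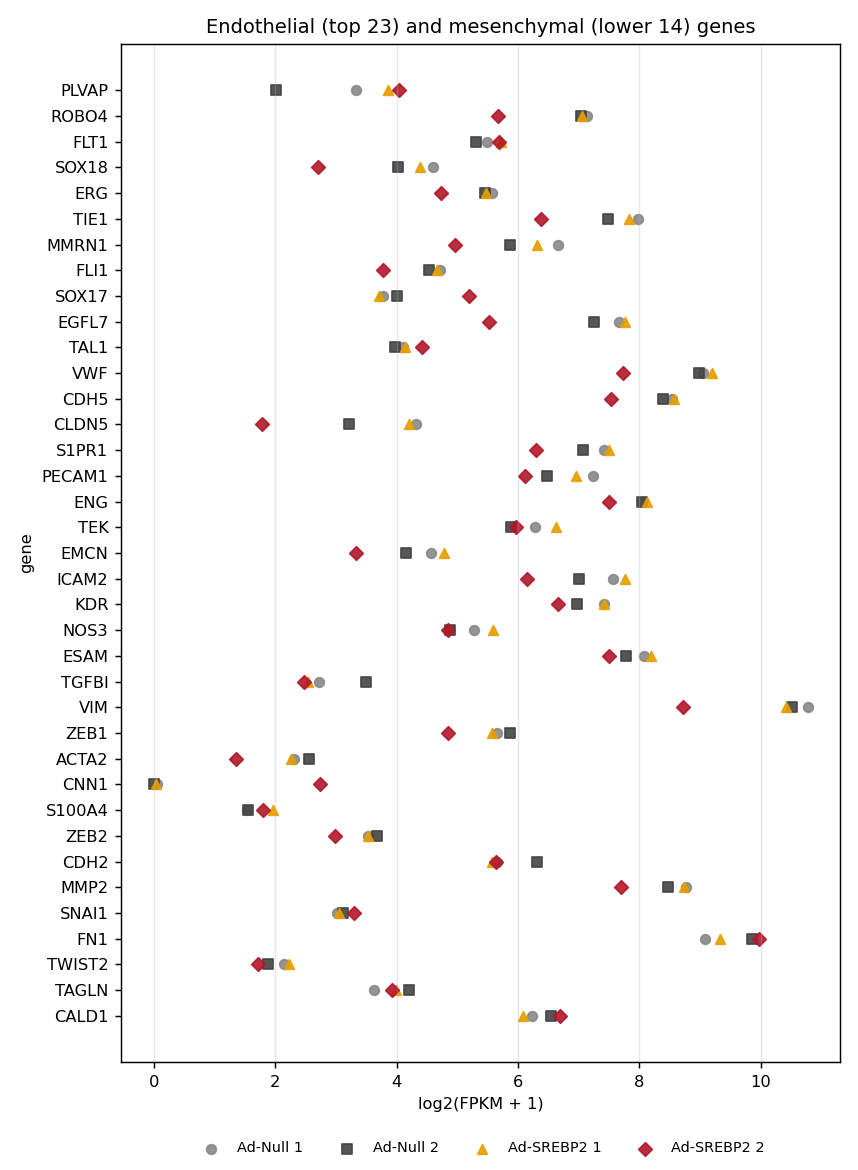
Expression of 23 endothelial identity genes (upper rows) and 14 mesenchymal genes (lower rows), as log2(FPKM + 1) on the horizontal axis. Each marker is 1 library (circles and squares, Ad-Null; triangles and diamonds, Ad-SREBP2 replicates 1 and 2), and the diamond is the lowest in 18 of the 23 endothelial genes, while none of the genes shown passed in limma with all 4 libraries.

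Leukocyte adhesion and cytokine genes did not pass as a list (camera adjusted p = 0.801), with a median log2 change of -0.01 while camera placed the list above the other genes. ICAM1, an adhesion molecule for leukocytes, was at 85.5 ± 50.9 FPKM in Ad-Null and 187 ± 114 FPKM in Ad-SREBP2, CCL2 at 118 ± 37.7 against 82.1 ± 13.1 FPKM, and the colony-stimulating factors CSF3 and CSF2 at 5.18 ± 2.78 against 1.59 ± 0.579 and 8.82 ± 5.22 against 2.90 ± 2.18 FPKM (SD, n = 2 each). The control libraries differed in these genes, with 20 of 21 higher in Ad-Null replicate 2 than in replicate 1, and CXCL8 at 83.5 and 284 FPKM. The list fell without Ad-Null replicate 1 (median -0.23, camera adjusted p = 0.00674) or Ad-SREBP2 replicate 2 (median -0.26, camera adjusted p = 0.00812), and rose without Ad-Null replicate 2 (median 0.30, camera adjusted p = 0.00589). Its median was 0.39 without Ad-SREBP2 replicate 1 (camera adjusted p = 0.108). Inflammasome and NADPH oxidase genes fell as a list at a median log2 change of -0.49 (camera adjusted p = 0.0283; adjusted p = 0.810 with an estimated correlation), a call that ended without Ad-SREBP2 replicate 2 (median -0.06, camera adjusted p = 0.200), against a median of -0.90 without replicate 1. It also ended with no filter on low values and with a mean of at least 5 FPKM (median -0.34 in both, camera adjusted p = 0.667 and 0.187). NOX4, an oxidase that makes hydrogen peroxide, was at 6.77 ± 0.314 against 2.48 ± 2.35 FPKM, and CYBA, its partner subunit, at 45.1 ± 5.64 against 20.2 ± 17.7 FPKM (SD, n = 2 each). PYCARD and GSDMD had log2 changes of -0.76 and -0.80. With limma, 0 of the 21 leukocyte genes and 0 of the 10 inflammasome and oxidase genes passed over all genes tested or adjusted over the list alone. When Ad-SREBP2 replicate 1 was left out, NOX4, CYBA, PYCARD and GSDMD had log2 changes of -2.09, -2.40, -1.35 and -1.56. With replicate 2 left out instead, these changes were -0.60, -0.44, -0.17 and -0.03.

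Other lists rose in camera with a preset correlation. These were NRF2 and oxidative response genes (median log2 change 0.43, camera adjusted p = 3.03e-05; adjusted p = 0.474 with an estimated correlation), histones (1.62, 3.94e-06; adjusted p = 0.599 with an estimated correlation) and heat shock genes (0.40, 0.00359; adjusted p = 0.599 with an estimated correlation). Without Ad-SREBP2 replicate 2 the medians of histones and heat shock genes were 0.51 and 0.08, and without replicate 1 they were 3.07 and 0.705. With no filter on low values the medians of histones and NRF2 genes were 1.06 and 0.25. Lysosome and autophagy genes (0.24, 0.00359; adjusted p = 0.474 with an estimated correlation) and the SREBP2 processing genes (0.23, 0.0177; adjusted p = 0.474 with an estimated correlation) did so too, the latter not without Ad-SREBP2 replicate 1 (median 0.37, camera adjusted p = 0.169). Without Ad-SREBP2 replicate 2 the medians of these 2 lists were 0.10 and 0.08, and that of lysosome genes was 0.34 without replicate 1. The SREBP2 processing list holds SREBF2 itself, and INSIG1, SREBF1 and SREBF2 rose in limma when adjusted over that list alone (1 of the 3 with either Ad-Null library left out), while 0 members of the NRF2, histone, heat shock, lysosome, DNA replication, unfolded protein response, immediate early, hypoxia and ribosomal protein lists did. The median of NRF2 genes was 0.555 without Ad-SREBP2 replicate 1 and 0.381 without replicate 2. DNA replication genes (0.20, 0.0283; adjusted p = 0.741 with an estimated correlation), unfolded protein response genes (0.18, 0.0283; adjusted p = 0.578 with an estimated correlation) and immediate early genes (0.43, 0.0372; adjusted p = 0.523 with an estimated correlation) did not pass without Ad-SREBP2 replicate 2 (medians -0.03, 0.05 and 0.14, camera adjusted p = 0.988, 0.200 and 0.143) or with no filter on low values (medians 0.14, 0.175 and 0.25, camera adjusted p = 0.104, 0.0786 and 0.0700). Their medians were 0.46, 0.41 and 1.28 without Ad-SREBP2 replicate 1, and that of DNA replication was 0.07 without Ad-Null replicate 2. Unfolded protein response genes also did not pass without Ad-Null replicate 1 (camera adjusted p = 0.0761). Hypoxia and glycolysis genes (median 0.01, 0.0404; adjusted p = 0.491 with an estimated correlation) did not pass without Ad-SREBP2 replicate 1 (median 0.06, camera adjusted p = 0.0850) or Ad-Null replicate 2 (median -0.05, camera adjusted p = 0.0715), nor with no filter (median 0.03, camera adjusted p = 0.0796), and had medians of 0.11 without Ad-Null replicate 1 and 0.07 without Ad-SREBP2 replicate 2. Quantile normalization ended the calls of the unfolded protein response, hypoxia and immediate early lists (camera adjusted p = 0.0540, 0.0537 and 0.0766), and a mean of at least 5 FPKM that of immediate early genes (camera adjusted p = 0.0937). Ribosomal protein genes fell (median -0.58, camera adjusted p = 0.000162; adjusted p = 0.867 with an estimated correlation), but not without Ad-SREBP2 replicate 2 (median -0.01, camera adjusted p = 0.877), with a median of -1.16 without replicate 1.

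The remaining lists did not pass. Median log2 changes were -0.16 for TGF-beta and BMP signalling, -0.30 for matrix and remodelling, -0.08 for antigen presentation, -0.07 for p53 targets, -0.28 for oxidative phosphorylation, -0.26 for Notch and arterial genes and -0.38 for venous and lymphatic genes (camera adjusted p = 0.876, 0.432, 0.747, 0.733, 0.208, 0.438 and 0.626). Without Ad-SREBP2 replicate 2 these 7 medians were -0.02, 0.04, 0.16, -0.02, 0.075, -0.03 and 0.16, so that 4 turned above 0, and without replicate 1 they were -0.18, -0.59, -0.29, -0.13, -0.57, -0.655 and -0.93. Medians were -0.54 for haemostasis, -0.69 for vasoactive genes, -0.40 for YAP targets and -0.13 for apoptosis (camera adjusted p = 0.167, 0.0764, 0.109 and 0.876). Without Ad-SREBP2 replicate 2 these 4 were -0.19, -0.06, -0.07 and -0.02, and without replicate 1 they were -1.275, -1.24, -0.68 and -0.26. Without Ad-Null replicate 1 the medians of p53 targets, oxidative phosphorylation, Notch and arterial, venous and lymphatic, and vasoactive genes were 0.01, -0.08, -0.12, -0.01 and -0.36. Without Ad-Null replicate 2 those of TGF-beta and BMP signalling, antigen presentation, p53 targets, oxidative phosphorylation, and Notch and arterial genes were 0.05, -0.155, -0.03, -0.42 and -0.395. In that fit haemostasis, vasoactive, Notch and arterial, and oxidative phosphorylation genes passed as lower (camera adjusted p = 0.0361, 0.0122, 0.0210 and 0.0104). Haemostasis and YAP targets passed as lower without Ad-Null replicate 1 (camera adjusted p = 0.00812 and 0.0108), and antigen presentation as higher without Ad-SREBP2 replicate 2 (camera adjusted p = 0.0488). In 6 of the lists that did not pass, among them TGF-beta and BMP signalling and p53 targets, the median was below 0 and the camera direction was higher. With no filter on low values the medians of TGF-beta and BMP signalling, venous and lymphatic genes and YAP targets were -0.09, -0.08 and -0.205. Vasoactive genes passed as lower with no filter (median -0.24, camera adjusted p = 0.0265) and at a mean of at least 5 FPKM (camera adjusted p = 0.0461). Haemostasis and vasoactive genes also passed as lower with the replicate number as a block (camera adjusted p = 0.0300 and 0.00991) and with arrayWeights (camera adjusted p = 0.0222 and 0.0357).

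Markers of other cell types were also measured. Smooth muscle markers had a median log2 change of -0.11 (5 tested) and epithelial markers of -0.16 (6 tested), and neither passed (camera adjusted p = 0.652 and 0.876), with a mean above 0 in the former (0.24). Their medians were 0.15 and 0.09 without Ad-SREBP2 replicate 2, -0.38 and -0.41 without replicate 1, 0.11 and -0.03 without Ad-Null replicate 1, and -0.34 and -0.28 without Ad-Null replicate 2, and -0.006 and 0.017 with no filter on low values. Only 2 fibroblast and 2 leukocyte markers reached a mean of 1 FPKM, too few for the list test, with medians of 1.22 and 0.21. With no filter on low values the leukocyte markers passed as higher (median 0.13, camera adjusted p = 0.0427), and the fibroblast markers did not pass (median -0.01, camera adjusted p = 0.957). LUM, a proteoglycan made by fibroblasts, was at 1.56 and 0.544 FPKM in Ad-Null and at 3.76 and 51.9 FPKM in Ad-SREBP2. KRT19 was at 2.89 and 1.47 FPKM in Ad-Null and 7.55 and 21.8 FPKM in Ad-SREBP2, and KRT7, another epithelial keratin, at 38.7 and 59.5 against 27.0 and 4.80 FPKM.

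**Figure D4:**
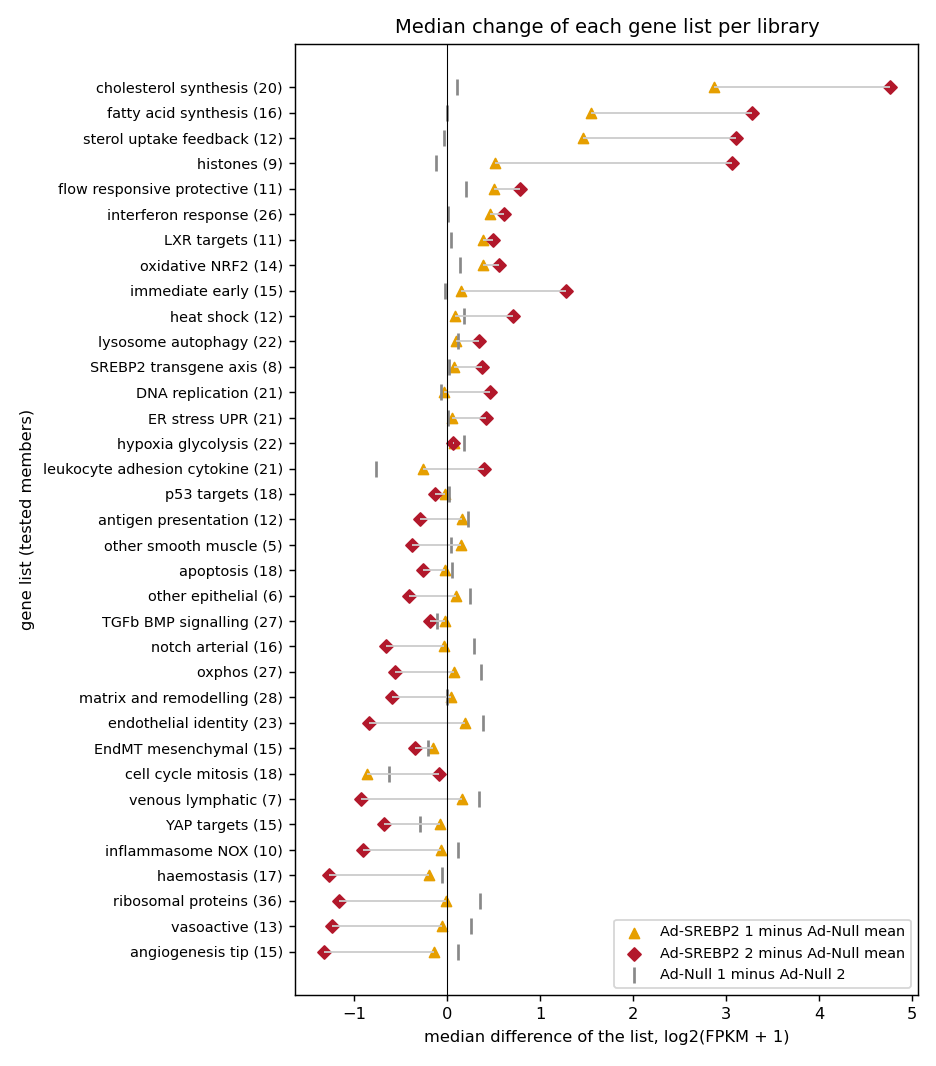
Median difference in log2(FPKM + 1) of each gene list with at least 3 tested members, with the number of members in parentheses. Triangles are Ad-SREBP2 replicate 1 and diamonds replicate 2, each minus the Ad-Null mean, and vertical ticks are Ad-Null replicate 1 minus replicate 2; the sterol and fatty acid lists lie highest in replicate 1 at 2.87, 1.54 and 1.46, and replicate 2 lies apart from replicate 1 in histones (3.07 against 0.51) and ribosomal proteins (-1.16 against -0.01).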

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

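The fits without small RNA loci, that with arrayWeights and those without small RNA loci and 1 Ad-SREBP2 library were chosen after the data were seen. The counts of 1 locus higher and 2 lower in limma were the same at a pseudocount of 0.1, with upper-quartile scaling, with quantile normalization and without a variance trend, and the cause of each change listed here was not tested. They were 0 and 0 at a pseudocount of 0.01 (249 higher and 57 lower at an unadjusted p under 0.05), with no filter (265 and 244), at a mean of at least 5 FPKM (152 and 31) and with small RNA loci left out (204 and 48). They were 25 and 3 with the replicate block (6 of these 28 were small RNA loci), with 9 of 20 cholesterol synthesis, 4 of 12 sterol uptake and 4 of 16 fatty acid genes higher over all genes. Over the list alone the block gave 4 of 26 interferon, 4 of 9 histone, 2 of 22 hypoxia, 1 of 14 NRF2 and 3 of 11 LXR genes higher (0, 0, 0, 0 and 2 without it). It gave 4 of 15 angiogenesis, 1 of 18 mitosis and 1 of 16 Notch and arterial genes lower (1, 0 and 0 without it). Of 6 epithelial markers, 1 rose and 2 fell with the block. Deviations of same-numbered libraries correlated across genes at 0.193 in 2 pairs, changes outside the SREBP lists at 0.559 with same-numbered and 0.219 with crossed controls, and RMRP and RPPH1 were lower in replicate 2 of both groups, so whether the numbers pair the libraries is left open. They were 32 and 0 with arrayWeights (557 and 126 unadjusted), and with small RNA loci left out 2225 and 3731 without Ad-SREBP2 replicate 1 and 135 and 16 without replicate 2. Leaving out 1 library in turn gave 0 to 1976 loci higher and 0 to 3028 lower, and 3 to 8 lists lower against 4 (7 without Ad-Null replicate 1, 8 without Ad-Null replicate 2). The lists higher numbered 12 to 15 under every alternative but 2: with an estimated correlation and with fry 0 lists were higher and 0 lower. The medians of cholesterol synthesis, sterol uptake and fatty acid synthesis are by construction unchanged there at 3.83, 2.30 and 2.42, with adjusted p = 0.474 for each with an estimated correlation and 0.296 with fry (limma). SREBF2 in Ad-SREBP2 against Ad-Null ranged from 1.76 to 3.80 in the fits without 1 library and passed with either Ad-SREBP2 library left out. Leave-one-out medians ran from -0.845 to 0.19 for endothelial identity genes, from -0.858 to 0.019 for mitosis genes and from -0.255 to 0.392 for leukocyte adhesion and cytokine genes, whose median was -0.048 with no filter and -0.014 with fry, both with the direction lower. Without Ad-SREBP2 replicate 2 the changes of SOX18, TIE1, MMRN1 and FLI1 turned to 0.067, 0.09, 0.054 and 0.048, from lowest values of -1.61, -1.35, -1.30 and -0.85 without replicate 1. Of 1067 values of named genes and other lists compared, 925 kept their direction and side of the threshold, 114 newly passed (58 without Ad-SREBP2 replicate 1), 17 no longer passed and 11 turned direction. The test chosen for a file of counts was not run, since the file holds FPKM. Depth limits SNORD105, MIR126 and MIR4517, where the values taken as 1 fragment were 28.5 to 46.4 FPKM.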

Other observations

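The tests of 1 fragment, of SREBP2 amount and of RNA without a poly(A) tail, the shares outside the SREBP lists, and the LUM, MALAT1, RMRP and RPPH1 values were chosen after the results were seen, and the tests of 1 fragment and of RNA without a poly(A) tail were also revised once after a first outcome.

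Several genes of the heat shock, immediate early and lysosome lists stood highest in Ad-SREBP2 replicate 2. DNAJB1, a co-chaperone, was at 35.9 and 30.6 FPKM in Ad-Null and at 60.2 and 435 FPKM in Ad-SREBP2, and HSPA1A, an inducible HSP70, at 5.61 and 5.38 against 9.56 and 82.0 FPKM, although its reads were not separated with certainty from those of its copy HSPA1B. ATF3 was at 38.2 and 53.5 against 70.5 and 501 FPKM, FOS at 0.0695 and 0.228 against 0.693 and 19.8 FPKM, and NR4A2 at 0.136 and 0.156 against 0.531 and 27.0 FPKM. Among lysosomal genes LIPA, which splits cholesteryl esters, was at 12.4 and 7.28 against 29.6 and 105 FPKM, CTSL at 93.6 and 74.0 against 169 and 491 FPKM, and GLA at 8.16 and 7.53 against 19.0 and 297 FPKM. With all 4 libraries none of these genes passed in limma. In fits chosen after the data were seen, with small RNA loci left out, LIPA and GLA rose in limma both without Ad-SREBP2 replicate 2 (adjusted p = 0.00664 and 0.00677) and without replicate 1 (adjusted p = 1.43e-06 and 4.75e-09), and these fits share the Ad-Null libraries. With small RNA loci kept, 0 of 22 lysosome genes passed over all genes without replicate 2.

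In the NRF2 list ME1, the malic enzyme, which is also in the fatty acid list, was at 11.5 and 13.9 FPKM in Ad-Null and 37.7 and 137 FPKM in Ad-SREBP2, and PGD, of the pentose phosphate pathway, at 139.6 and 109 against 204 and 456 FPKM. With arrayWeights 9 genes outside the 3 SREBP lists rose (limma), among them FABP3, UCP2, a mitochondrial carrier, and C14orf1. Among lists that fell, all 36 ribosomal protein genes were lower in Ad-SREBP2 replicate 2 than in every other library, with RPL10A at 722 and 613 FPKM in Ad-Null and 594 and 165 FPKM in Ad-SREBP2; reads of this family were not separated with certainty between copies. RMRP stood at 219, 37.1, 141 and 18.6 FPKM and RPPH1 at 118, 13.6, 101 and 11.99 FPKM in Ad-Null replicates 1 and 2 and Ad-SREBP2 replicates 1 and 2.

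The loci called in the planned test were 3 small RNA loci at 0 in one group. In 3 of 3 the depth-scaled values are 1.0 to 1.052 times the value taken as 1 fragment at their length (lengths from a later build than that of the values). That value was the median of the lowest values of small RNA loci of similar length, the called locus included, so the comparison is partly circular. A group of equal single fragments would have almost no spread, and these calls may reflect chance detection. A first version compared with the lowest value at similar length, with ratios of 1.105 to 1.416 under a limit of 1.5 in 3 loci, and read the same. No biological explanation was tested.

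The Ad-SREBP2 replicate 2 library stood apart from replicate 1. Shallower sequencing is argued against by a ratio of 3.18 (95% bootstrap interval over genes 2.83 to 3.5) between the SDs of the Ad-SREBP2 and Ad-Null pairs in 3799 genes of at least 20 FPKM, gene length bias by 1.63% of the variance explained (1.23 to 2.08; lengths for 98.2% of genes, from a later build than that of the values), and admixed fibroblasts as the whole cause by COL1A1, COL1A2, COL3A1 and DCN, of which the highest was 0.715 FPKM. Going with fibroblasts, that value was COL1A1, at 0.0065 to 0.0215 FPKM in the other libraries, and LUM was at 51.9 against 0.544 to 3.76 FPKM, so a small share of them is left open. A candidate explanation is more SREBP2 in replicate 2, with SREBF2 at 4.17 times its level in replicate 1. Virus reads were not separated from those of the cell's own SREBF2, itself a member of the sterol feedback list, so this ratio does not measure delivered SREBP2. In replicate 2, 95.7% (44 of 46) of SREBP list members were farther from Ad-Null, against 53.7% of 11556 genes outside the lists. But 96 genes outside them were picked as higher in the fit without replicate 2 and small RNA loci, and 86 of these were farther in replicate 2 too. Specificity to SREBP targets was not tested. Outside the lists the changes of the replicates, each against its own control, correlated across genes, which are not independent replicates, at 0.559 with same-numbered controls and 0.219 with crossed ones, so that more SREBP2 and a difference in culture or donor cannot be told apart there; viral load was not measured.

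Histone genes were higher in Ad-SREBP2 replicate 2 than in replicate 1 in 9 of 9 tested, out of 18 listed. HIST1H2AC was at 5.40 and 4.00 FPKM in Ad-Null and 8.85 and 55.1 FPKM in Ad-SREBP2, where reads may be split between copies. The filter used the mean over all 4 libraries, so high values in replicate 2 helped members to be tested, and the count of 9 of 9 was partly fixed by it. Members below the filter stood at 0 to 0.437 FPKM in replicate 1 and 0 to 1.02 FPKM in replicate 2. More RNA without a poly(A) tail in replicate 2 is argued against only for 45 small RNA loci above 0 in every library. Their median log2 difference between the Ad-SREBP2 libraries was -0.057 (95% bootstrap interval -0.736 to 0.25). Loci at 0 in any library were left out, so RNA first detected in replicate 2 could not enter this test. RMRP and RPPH1 were lower in replicate 2 of both groups. MALAT1, whose mature end has no poly(A) tail, went with this explanation, at 44.6 and 52.5 FPKM in Ad-Null and 45.5 and 108.5 FPKM in Ad-SREBP2, so such RNA was not excluded. A first version over all 167 small RNA loci gave a median of 0.0 (0.0 to 0.0) and was void, since 42 of them were at 0 in both libraries. DNA replication genes did not move alike in both replicates (median -0.03 and 0.46), and a cell cycle explanation was not tested.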
